A study of Mus musculus with 12 samples.

How the data were processed

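RNA sequencing libraries came from MC3T3-E1 mouse preosteoblasts grown in 10% serum, taken as day 0 at 2 days after confluence, and differentiated with or without mouse interferon beta (IFN, 50 mg/L per the labels) to day 14 or day 21. There were 12 libraries in 6 groups of 2. Each library was made from at least 3 µg of RNA with bead purification of mRNA. Per the submitters' processing notes, reads were aligned with HISAT2 to mm10, handled with SAMtools and counted per gene with featureCounts, without versions; the deposited table holds the resulting raw count of reads per gene and library. The notes give neither the annotation nor the use of strand, so values for overlapping or antisense genes and for close copies (Ifit3 and Ifit3b, the H2 genes, Hspa1a and Hspa1b, the Oas and Ifi200 families) are uncertain.

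The table has 55291 symbols, of which 53292 match GENCODE release M21, the source of the positions given. The 37 mitochondrial symbols all have 0 counts, so their share could not be used as a measure of quality. Library totals ran from 29772425 to 38908453 counts, and a gene with 0 counts in a group may still be expressed below that depth. Intervals and floors for genes with 0 to 3 counts in a group cover counting error only, and a floor sets the group at 3 counts.

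Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes kept by filterByExpr over the 6 groups (17289), TMM scaling, 1 mean per group, robust quasi-likelihood F tests with 6 residual degrees of freedom, and Benjamini-Hochberg adjusted p below 0.05 over all genes kept. "Called" means passing that limit. For IFN against control, "rose" and "fell" mean higher and lower with IFN than in control at the same day. Log2 CPM used a prior count of 2. CPM is given as mean ± SD of 2 libraries and fold changes as log2 ± SE. A gene does not overlap when both libraries of a group lie above both of the other, which chance gives for 33.3% of genes. Comparisons were IFN against control at each day and on average, day 14 against day 0 and day 21 against day 14 in each arm, and the change of the IFN effect with time.

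Gene lists were fixed before the data were examined: 27, of which 26 could be measured. They are interferon-stimulated, MHC class I, interferon receptor and JAK-STAT, osteoblast and bone matrix, mineralization, osteocyte, chondrocyte, adipocyte, muscle, macrophage and osteoclast, endothelial and epithelial, fibroblast and tendon, cell cycle, Wnt, BMP and TGF-beta, Notch, collagen processing and matrix remodelling, inflammatory, glycolysis and hypoxia, oxidative phosphorylation, endoplasmic reticulum stress, p53 and apoptosis, cholesterol synthesis, ribosomal protein, immediate early and heat shock, and osteoclast-regulating genes. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. Fry results are given for some lists only, each with an adjusted p below 0.05. Lists without a fry result should not be read as passing it. Member counts are given over all genes and adjusted over the list alone.

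The rule for named genes, the comparisons and the main alternatives were also fixed before the data were examined. Always named are Sox9, Ifnar1, Ifnar2, Runx2, Sp7, Alpl, Bglap and Col1a1. To these come the 6 highest and 6 lowest called genes by fold with a mean log2 CPM of at least 1 and no overlap, and up to 3 called members per list with the smallest adjusted p; predicted or unnamed genes are counted but not named. Results for some genes that the rule takes are not reported here. For the average, the IFN arm over time and the change of the IFN effect, the 5 highest and 5 lowest called genes are named. Dlx5, Dmp1, Spp1, CT010467.1, Hspa5, Fkbp5, Fos, Hmox1, Atf3, the uncalled list members Oas2, Ifi27, Isg20, Mx2 and Sp110, and the values of Bnip3 per library were chosen after values were seen.

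The alternatives were RLE scaling, library size alone, DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in 2 libraries, a fit with only the groups compared, a replicate block, an absolute log2 fold change of at least 1, and each library left out. Leaving out a library leaves a group of 1, which is assumed to vary like the other groups. The filter then keeps more genes of low count, so such values reflect both changes. Without control day 21 replicate 1, control day 21 is replicate 2 alone, a library set apart by stress genes. Calls that use control day 21 in that fit rest on that library. After the data were seen, a fit without control day 0 replicate 1 and control day 21 replicate 2 and a limma voom fit with library weights were added.

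The procedure was tested on simulated data. For recovery, all libraries had the same pooled spread per gene, unlike the real arms, and only genes with a mean above 2 CPM were changed. Of 100 genes changed 2-fold, edgeR recovered 24 for IFN at day 14, 23 at day 21, 18 for control day 14 against day 0 and 2 for the change of the IFN effect. Of 100 changed 4-fold it recovered 86, 83, 81 and 55. With nothing changed and the unequal spread of the arms simulated, 0 of 16666 genes were called for IFN against control and 5 for each step over time in control. With 1 of 26 lists shifted, camera at the preset correlation called that list and 1 list that was not shifted.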

Results

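RNA was sequenced from MC3T3-E1 cells, a mouse preosteoblast line, as they differentiated toward bone with or without mouse interferon beta (IFN), a type I interferon. Both arms were sampled at day 0, day 14 and day 21, with 2 libraries in each of the 6 groups. The labels give the IFN dose as 50 mg/L from the start of differentiation and do not say whether the day 0 libraries of the IFN arm had been exposed. The total count was 31845405 and 38908453 in the control day 0 libraries, 33615915 and 32018132 at day 14, and 33994237 and 33411108 at day 21. In the IFN arm it was 31738353 and 35193188 at day 0, 35425412 and 29772425 at day 14, and 34605553 and 34863250 at day 21. Between 20974 and 23633 genes had at least 1 count, and 17289 were tested.

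The control libraries varied more than the IFN libraries. The median SD of log2 CPM between the 2 replicates was 0.29, 0.24 and 0.44 in control at days 0, 14 and 21, and 0.08, 0.09 and 0.11 in IFN. The biological coefficient of variation was 0.392 across the 6 control libraries and 0.0642 across the 6 IFN libraries. Hspa5, the main chaperone of the endoplasmic reticulum, was at 25680 CPM in control day 21 replicate 2 and between 562.9 and 1828 CPM in the other 11 libraries. The annotated ribosomal RNA gene CT010467.1 was at 21080 CPM in control day 0 replicate 1 and at 1103 CPM in replicate 2. Bnip3, a hypoxia-induced mitophagy gene, was at 626.4 CPM in control day 14 replicate 1 and 91.24 CPM in replicate 2. The labels do not say that replicates are separate cultures, so each p may measure technical spread rather than spread between cultures.

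**Figure D1:**
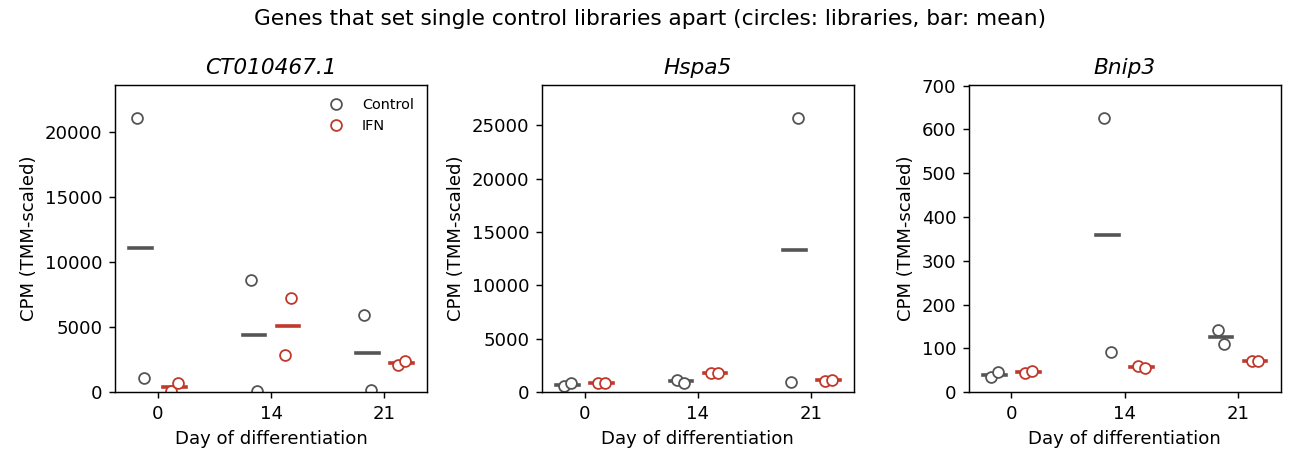
CPM of CT010467.1, Hspa5 and Bnip3 in each library by day of differentiation, control in grey and IFN in red; circles are libraries and bars are group means of 2 libraries. Single control libraries reach 21080 CPM for CT010467.1, 25680 CPM for Hspa5 and 626.4 CPM for Bnip3.

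The first question was what IFN did to differentiating cells at day 14. Interferon-stimulated genes were strongly higher in the IFN arm. Irf7, a transcription factor that amplifies type I interferon responses (mm10 chromosome 7, 141262706 to 141266481), was at 731 ± 15.7 CPM (SD, n = 2) with IFN and 4.95 ± 2.51 CPM in control, a log2 fold change of 7.21 ± 0.42 (SE) with an edgeR adjusted p = 4.48e-05. The chemokine gene Cxcl10 (chromosome 5, 92346638 to 92348889) was at 128 ± 5.49 against 3.64 ± 2.26 CPM (log2 5.14 ± 0.54, adjusted p = 0.000849). Both differences exceeded the spread between replicates, with both IFN libraries above both control libraries.

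Of the 53 measured interferon-stimulated genes, 50 rose and 0 fell at day 14, and 51 rose and 1 fell when adjusted over the list alone. The members that did not pass over all genes were Oas2 (log2 4.66, adjusted p = 0.0553), Ifi27 (log2 -1.65, adjusted p = 0.0767) and Isg20 (log2 -0.34, adjusted p = 0.85). The median of the list was 3.71 (camera adjusted p = 3.71e-94, and adjusted p = 0.0507 with an estimated correlation; fry adjusted p = 0.000265). Slfn4 had 387 counts in the IFN libraries and 1 in control, a ratio of 378.1 (95% interval 67.47 to 14970, counting error only). After Slfn4 and Irf7, the next genes by fold were the antiviral effectors Ifit3 (log2 7.02), Rsad2 (6.84) and Ifit3b (6.82), and then Oasl1 (6.54). Ifit3 and Ifit3b are close copies whose reads counting could split. The RNA sensor Dhx58 (4.87 ± 0.31, adjusted p = 5.14e-05) and the ubiquitin ligase Trim25 (2.53 ± 0.17, adjusted p = 6.03e-05) had the smallest adjusted p after Irf7 within the list. Oasl1 alone among these lost its call when control day 14 replicate 1 was left out (adjusted p = 0.0605).

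Several antigen presentation genes rose as well. Of 19 measured MHC class I genes, 11 rose at day 14 (17 adjusted over the list alone) and 0 fell, among them the peptide transporter gene Tap1 (log2 1.84 ± 0.23), the immunoproteasome subunit Psmb10 (2.40 ± 0.34) and H2-T22 (2.69 ± 0.21), whose reads may be shared with related H2 genes. The median of the list was 1.84 (camera adjusted p = 3.09e-23, and adjusted p = 0.0713 with an estimated correlation; fry adjusted p = 0.00227). Among 20 receptor and JAK-STAT genes, Irf5 (1.36 ± 0.28) and Irf1 (0.85 ± 0.19) rose, the same 2 adjusted over the list alone; the list median was -0.11 and its mean -0.02 while the camera direction was up (adjusted p = 0.933). The receptor genes had values near 0, with log2 -0.13 ± 0.23 for Ifnar1 (adjusted p = 0.858) and 0.05 ± 0.19 for Ifnar2 (adjusted p = 0.946). Of 24 inflammatory genes, Cxcl10 and the chemokine gene Ccl7 (1.83 ± 0.40) were higher with IFN, with 5 higher and 1 lower adjusted over the list alone. Ccl7 was at 62.8, 15.4 and 55.4 CPM in control at days 0, 14 and 21, and at 44.6, 54.5 and 60.7 CPM with IFN. Its difference at day 14 thus came with a low value in control at that day. The median of the inflammatory list was 0.13 (camera adjusted p = 0.0335, and adjusted p = 0.546 with an estimated correlation). That list call ended without control day 0 replicate 1 (0.0507), control day 0 replicate 2 (0.0608) or control day 14 replicate 1 (0.0912). Irf1 kept its own call in 4 of the 12 fits that leave out a library. Irf5 and Ccl7 kept it in 5.

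Several bone matrix genes were lower with IFN at day 14. Col1a1, the main collagen of bone (chromosome 11, 94936224 to 94953042), was at 1086 ± 4.72 CPM with IFN and 5252 ± 1920 CPM in control, 4.84-fold lower (log2 -2.27 ± 0.43, adjusted p = 0.0207). Ibsp, bone sialoprotein (chromosome 5, 104299171 to 104311469), was at 1.44 ± 1.16 against 17.2 ± 6.70 CPM (log2 -3.56 ± 0.64, adjusted p = 0.0202). Sparc, osteonectin (chromosome 11, 55394500 to 55423183), was at 1165 ± 15.7 against 2096 ± 233 CPM (log2 -0.85 ± 0.17, adjusted p = 0.0308). Of the 25 osteoblast and bone matrix genes, 4 fell and 0 rose (10 fell and 0 rose adjusted over the list alone); the fourth was Dlx5, an osteoblast transcription factor (log2 -1.45 ± 0.30, adjusted p = 0.0321), named after its value was seen. The list median was -0.70 (camera adjusted p = 9.04e-06, and adjusted p = 0.176 with an estimated correlation; fry adjusted p = 0.0267). Values for Runx2 (log2 -0.11 ± 0.22, adjusted p = 0.878), Sp7 (-0.86 ± 0.36, adjusted p = 0.308), Alpl (-1.89 ± 0.68, adjusted p = 0.229) and Bglap (0.57 ± 1.01, adjusted p = 0.867) did not pass. Alpl did pass with DESeq2 (adjusted p = 0.046), no filter (1.4e-05) or without both outlying control libraries (0.00257), and Sp7 without both outlying control libraries (0.0314). These libraries are control day 0 replicate 1 and control day 21 replicate 2. That fit and the fit with library weights were chosen after the results were seen. The Col1a1 call ended without control day 14 replicate 1 (adjusted p = 0.136), IFN day 14 replicate 1 (0.199) or IFN day 14 replicate 2 (0.217), and the Ibsp call without control day 14 replicate 1 (0.116), IFN day 14 replicate 2 (0.148) or with only the groups compared (0.0525). The Sparc call held in 4 of the 12 fits that leave out a library, with adjusted p from 0.00262 to 0.319.

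**Figure D2:**
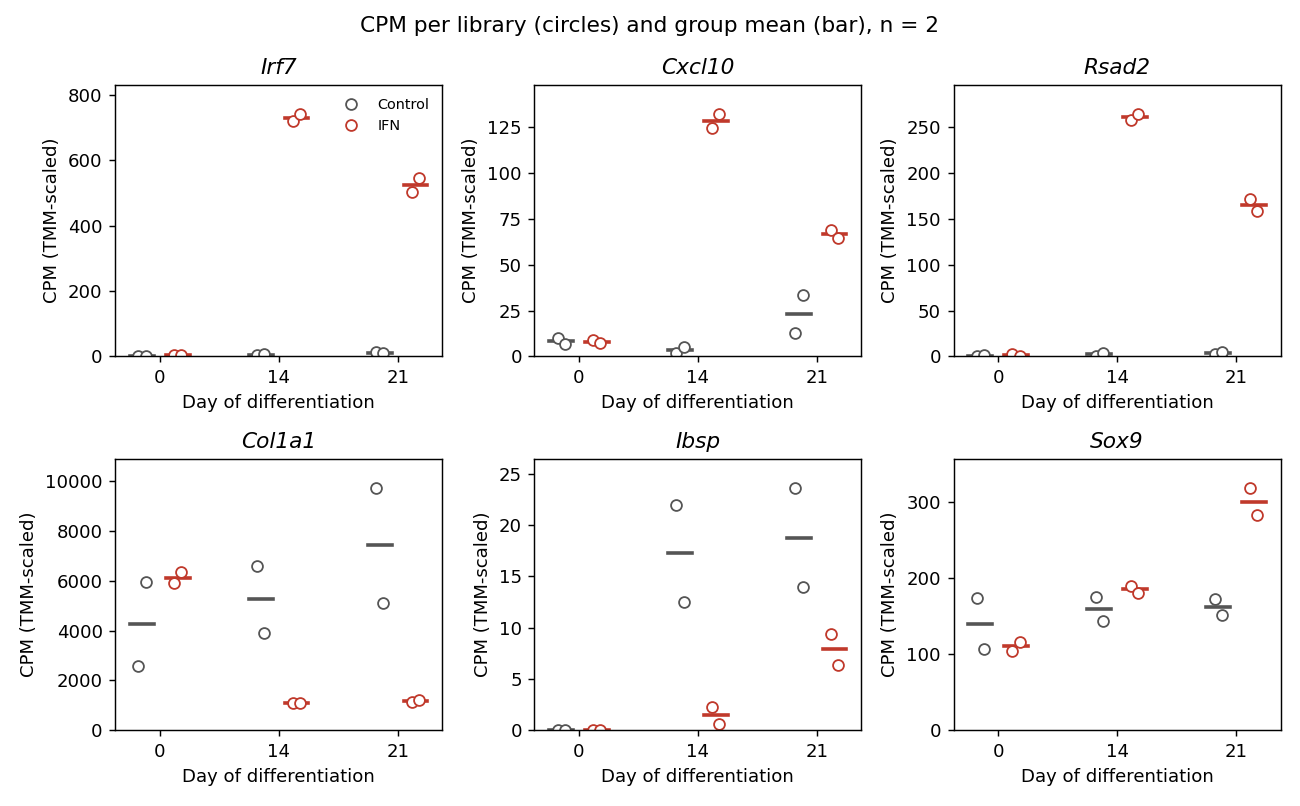
CPM of Irf7, Cxcl10, Rsad2, Col1a1, Ibsp and Sox9 by day of differentiation, control in grey and IFN in red; circles are libraries and bars are group means of 2 libraries. Irf7 reached 731 CPM with IFN at day 14 against 4.95 CPM in control, and Col1a1 was at 1086 CPM against 5252 CPM.

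Other matrix and signalling lists at day 14 had fewer calls. Of 25 collagen processing and matrix remodelling genes, the lysyl oxidase family member Loxl3 rose (log2 0.89 ± 0.19), and the prolyl hydroxylase subunit P4ha3 (-1.12 ± 0.23) and the gelatinase Mmp2 (-1.004 ± 0.23) fell; adjusted over the list alone 1 rose and 10 fell, and the median was -0.55 (camera adjusted p = 9.04e-06, and adjusted p = 0.338 with an estimated correlation). Of 22 Wnt genes, the co-receptor Lrp5 (-1.32 ± 0.20) and the feedback inhibitor Axin2 (-1.80 ± 0.33) were lower with IFN, 7 adjusted over the list alone. The median of the Wnt list was -0.53 (camera adjusted p = 2.66e-06, adjusted p = 0.181 with an estimated correlation, and fry adjusted p = 0.0267). Lrp5 was at 148.4, 462.4 and 254.7 CPM in control at days 0, 14 and 21, and at 158.8, 185.3 and 243.3 CPM with IFN. Of 15 fibroblast and tendon markers, Col6a1 (-1.58 ± 0.28) and Col5a1 (-1.51 ± 0.28) fell, 5 adjusted over the list alone, with a median of -0.43 (camera adjusted p = 0.0022, and adjusted p = 0.546 with an estimated correlation). Of 24 glycolysis and hypoxia genes, Egln3, an oxygen-sensing prolyl hydroxylase, fell (-3.32 ± 0.63), 16 adjusted over the list alone, with a median of -1.15 (camera adjusted p = 7.48e-08, and adjusted p = 0.546 with an estimated correlation). Control day 14 replicate 1 stood apart in this list, with a median log2 CPM of 9.25 against 7.27 in replicate 2. Without that library the list median was -0.27 and its adjusted p = 0.0523, and Egln3 lost its call (log2 -1.67, adjusted p = 0.0996). Loxl3 and Mmp2 kept the call in 4 of the 12 fits that leave out a library. Egln3 and P4ha3 kept it in 5. Col6a1 kept it in 8, Col5a1 and Axin2 in 9 and Lrp5 in 10.

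Single members of further lists were called at day 14. Col11a1 fell (log2 -2.28 ± 0.37) among 17 chondrocyte genes, with 1 higher and 3 lower adjusted over the list alone. Irx5 fell (-1.27 ± 0.26) among 10 osteocyte markers, 1 adjusted over the list alone. Ibsp was also the only call among 15 mineralization genes, with 1 higher and 1 lower adjusted over the list alone. The fatty acid carrier Fabp4 was lower with IFN (-1.48 ± 0.32) among 10 adipocyte markers, 2 adjusted over the list alone. Between day 0 and day 14 its mean went from 1.65 to 20.8 CPM in control and from 0.91 to 7.43 CPM with IFN. The growth factor gene Ccn2 rose (1.56 ± 0.35) among 24 BMP and TGF-beta genes, with 1 higher and 2 lower adjusted over the list alone. Of 22 p53 and apoptosis genes, the necroptosis effector Mlkl rose (1.34 ± 0.24) and Sesn1 fell (-1.47 ± 0.28), with 6 higher and 2 lower adjusted over the list alone. In edgeR, 0 members were called among 9 muscle, 9 macrophage and osteoclast, 8 endothelial and epithelial, 30 cell cycle, 10 Notch, 23 oxidative phosphorylation, 20 endoplasmic reticulum stress, 19 cholesterol synthesis, 25 ribosomal protein, 20 immediate early and heat shock and 10 osteoclast-regulating genes. Adjusted over the list alone, 2 Notch genes were lower and 1 endoplasmic reticulum stress gene was higher, and the other 9 of these 11 lists had 0. None of the lists in this paragraph passed camera at day 14 (lowest adjusted p = 0.0812, for the adipocyte markers). Ccn2 kept its call in 3 of the 12 fits that leave out a library (log2 from 1.07 to 2.33). Irx5 kept it in 5, Fabp4 in 6 and Col11a1, Mlkl and Sesn1 in 9.

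Over all genes at day 14, edgeR called 396, 224 higher and 172 lower with IFN. Among the lowest folds by the naming rule were those of Megf6 (log2 -4.12 ± 0.58), the axon guidance gene Draxin (-3.86 ± 0.63), Tspan18 (-3.83 ± 0.60), Mrgprf (-3.67 ± 0.52) and Ibsp. Megf6, Draxin, Tspan18 and Ibsp kept the call in 10 of the 12 fits that leave out a library and Mrgprf in 11. The groups did not overlap for 55.7% of genes, where chance gives 33.3%. All 396 called genes were among these, so leaving out 1 library could hardly turn their direction. DESeq2 called 998. More genes were lower than higher with DESeq2 (385 higher and 613 lower), no filter (443 and 732), library weights (686 and 981), only the groups compared (321 and 336) and without both outlying control libraries (1259 and 1492). The same held without control day 0 replicate 1 (265 and 268), control day 14 replicate 2 (196 and 296), control day 21 replicate 1 (513 and 676) and control day 21 replicate 2 (533 and 664). The count was 178 without control day 14 replicate 1, 1189 and 1197 without control day 21 replicate 1 or 2, 240 and 246 without IFN day 0 replicate 1 or 2, 124 and 114 without IFN day 14 replicate 1 or 2, and 248 and 243 without IFN day 21 replicate 1 or 2. Of the 36 named genes called at day 14, 35 kept the call without either control day 0 library, 20 and 27 without control day 14 replicate 1 or 2, 36 without either control day 21 library, 25 without either IFN day 0 library, 14 and 12 without IFN day 14 replicate 1 or 2, and 26 and 25 without IFN day 21 replicate 1 or 2; 0 changed direction.

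At day 21 the interferon response was still present. Irf7 was at 525 ± 29 CPM with IFN and 12.2 ± 2.11 CPM in control (log2 5.43 ± 0.38, adjusted p = 0.000202). Pax5, best known as a B cell transcription factor (chromosome 4, 44524757 to 44710487), had the highest fold by the naming rule, at 11.2 ± 3.58 against 0.103 ± 0.0635 CPM (log2 6.76 ± 0.57, adjusted p = 5e-04). Its control level was near the floor, so the size of this fold is uncertain. Plac8 (6.38 ± 1.06), the interferon-induced GTPase Tgtp1 (5.97 ± 0.76), Slfn4 (5.81 ± 0.82) and Rsad2 (5.42 ± 0.59) followed. Plac8 kept its call in 9 of the 12 fits that leave out a library, with log2 from 5.29 to 11.64. Tgtp1 and Slfn4 kept it in 11. Of the 53 interferon-stimulated genes, 48 rose and 0 fell (51 rose and 1 fell adjusted over the list alone), with a median of 3.19 (camera adjusted p = 1.23e-84, and adjusted p = 0.0693 with an estimated correlation; fry adjusted p = 0.000828). The 5 that did not pass were Oas2, Mx2, Sp110, Ifi27 and Isg20. Dhx58 (3.37 ± 0.29) and Trim25 (1.96 ± 0.16) were again among the smallest adjusted p. Of the 19 MHC class I genes, 7 rose, among them B2m (1.72 ± 0.20), Tap1 (1.93 ± 0.23) and H2-T22 (2.18 ± 0.21), with 17 higher and 2 lower adjusted over the list alone and a median of 1.72 (camera adjusted p = 9.18e-18, and adjusted p = 0.133 with an estimated correlation; fry adjusted p = 0.00502). With only the groups compared these calls ended: B2m (adjusted p = 0.226), Tap1 (0.207), H2-T22 (0.0883), Trim25 (0.0838), Pax5 (0.0693), Tgtp1 (0.0693), Slfn4 (0.0693) and Plac8 (0.331).

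**Figure D3:**
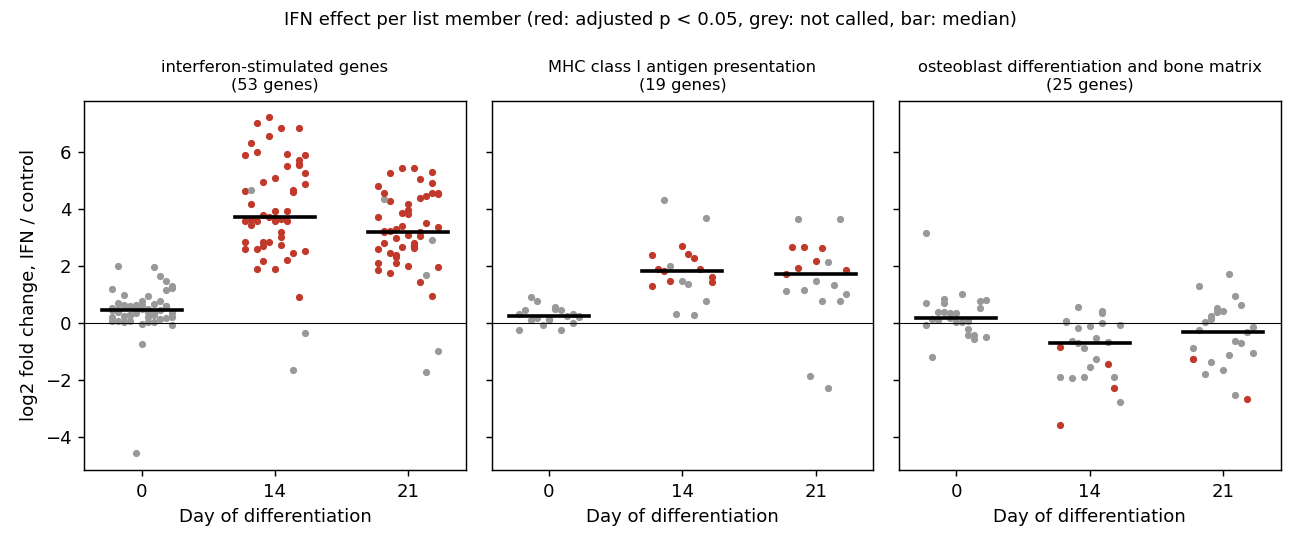
Log2 fold change of IFN over control for each measured member of the interferon-stimulated, MHC class I and osteoblast lists at days 0, 14 and 21; red points passed adjusted p of 0.05, grey points did not, and bars are medians. The median of the 53 interferon-stimulated genes was 0.46 at day 0, 3.71 at day 14 and 3.19 at day 21.

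Col1a1 and Sparc were lower with IFN at day 21 as well. Col1a1 was at 1178 ± 44.2 CPM with IFN and 7418 ± 3270 CPM in control (log2 -2.65 ± 0.43, adjusted p = 0.0157), and Sparc at 938.8 ± 68.9 against 2253 ± 8.27 CPM (log2 -1.26 ± 0.17, adjusted p = 0.00602). These were the 2 of 25 osteoblast and bone matrix genes that fell, with 0 higher; 1 rose and 4 fell adjusted over the list alone, and the list did not pass camera (median -0.31, adjusted p = 0.0792). Values for Runx2 (log2 0.42 ± 0.22, adjusted p = 0.438) and Sp7 (0.51 ± 0.36, adjusted p = 0.574) were positive and did not pass. Alpl (-0.88 ± 0.66, adjusted p = 0.605), Bglap (-1.37 ± 0.96, adjusted p = 0.58), Ifnar1 (-0.25 ± 0.23, adjusted p = 0.671) and Ifnar2 (0.21 ± 0.19, adjusted p = 0.67) did not pass either. Bglap passed without control day 21 replicate 1 (log2 -2.31), where replicate 2 was the only control, and turned sign without control day 21 replicate 2 (log2 2.21). Alpl (0.23) and Ifnar2 (-0.0268) turned sign without that library too, and Ifnar1 without control day 21 replicate 1 (0.23). Ifnar1 passed without both outlying control libraries (adjusted p = 0.0205). Tnn, the matrix protein tenascin N (chromosome 1, 160085029 to 160153580), was at 19.0 ± 7.93 against 367.6 ± 106 CPM (log2 -4.28 ± 0.34, adjusted p = 0.000351). The collagen-binding proteoglycan Fmod (-5.81 ± 1.01) was called among 17 chondrocyte genes, with 1 higher and 2 lower adjusted over the list alone, and Col5a1 (-1.64 ± 0.28) among 15 fibroblast markers, with 4 lower adjusted over the list alone. The extracellular chaperone Clu fell too (-3.45 ± 0.66). Col1a1, Sparc, Fmod, Clu and Col5a1 all lost the call without IFN day 21 replicate 1 or replicate 2 (Col1a1 adjusted p = 0.197 and 0.187), and Fmod and Clu also without control day 21 replicate 2 (log2 -3.97 and -1.84) and without any single IFN library of day 0 or day 14 (Fmod adjusted p from 0.0759 to 0.0842, Clu from 0.0916 to 0.0942). With only the groups compared, adjusted p was 0.246 for Col1a1, 0.395 for Sparc and 0.102 for Tnn.

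Sox9, the chondrocyte transcription factor that the study title names, was the other gene of interest at day 21 (chromosome 11, 112782224 to 112787760). It was at 300.7 ± 25.6 CPM with IFN and 162.4 ± 15.1 CPM in control, 1.85-fold higher (log2 0.89 ± 0.23) with both IFN libraries above both controls, and did not pass (adjusted p = 0.133). At day 14 it was at 185.3 ± 6.74 against 159.3 ± 22.4 CPM (log2 0.22 ± 0.22, adjusted p = 0.741), and at day 0 at 110.3 ± 8.63 against 140.3 ± 47.9 CPM (log2 -0.35 ± 0.22, adjusted p = 0.997). The day 21 difference did pass with DESeq2 (adjusted p = 0.0228), with no filter on low counts (0.0046), without control day 0 replicate 1 (0.0317) or replicate 2 (0.0314), without control day 21 replicate 1 (0.0222) and without both outlying control libraries (0.017). Over the alternatives run on named genes, its adjusted p ranged from 0.0046 to 0.708. The change of the IFN effect on Sox9 between day 14 and day 21 was not called (log2 0.67 ± 0.32, adjusted p = 0.652).

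Further day 21 calls fell in few lists. The BMP target Id1 rose (log2 1.41 ± 0.21) among 24 BMP and TGF-beta genes, with 1 higher and 2 lower adjusted over the list alone, and the death ligand Tnfsf10 rose (4.60 ± 0.80) among 22 p53 and apoptosis genes, 2 adjusted over the list alone. Id1 kept its call in 10 of the 12 fits that leave out a library and Tnfsf10 in 9. The heat shock genes Hspa1a (-7.74 ± 1.17) and Hspa1b (-6.68 ± 1.30), near-identical copies whose reads counting could split, were the 2 that fell among 20 immediate early and heat shock genes, 7 adjusted over the list alone. Their fold came mostly from control day 21 replicate 2, which had 354.9 CPM of Hspa1a and 6479 CPM of Hspa1b against 21.21 and 135.5 CPM in replicate 1. Without that library both were still called, at log2 -4.61 for Hspa1a (adjusted p = 0.00227) and -2.08 for Hspa1b. The Hspa1a call was lost without IFN day 21 replicate 1 (adjusted p = 0.208) or replicate 2 (0.198), and the Hspa1b call held in 2 of the 12 fits that leave out a library, with adjusted p up to 0.513. The 20 endoplasmic reticulum stress genes had a median of -2.27 (camera adjusted p = 8.51e-06, and adjusted p = 0.583 with an estimated correlation) with 0 called by edgeR and 15 lower adjusted over the list alone. Without control day 21 replicate 2 the direction turned, with a median of 0.13 and an adjusted p = 0.00846. Ribosomal protein genes behaved likewise (median -0.20, adjusted p = 0.0257, and adjusted p = 0.692 with an estimated correlation), with a median of 0.09 and adjusted p = 0.0486 without that library and adjusted p = 0.211 without IFN day 21 replicate 1.

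A further 3 lists passed camera at day 21 with 0 members called by edgeR. The collagen processing genes had a median of -0.54 (adjusted p = 0.00852, and adjusted p = 0.583 with an estimated correlation), with 2 lower adjusted over the list alone and an adjusted p = 0.637 without control day 21 replicate 1. The glycolysis and hypoxia genes had a median of -0.46 (adjusted p = 0.0153, and adjusted p = 0.674 with an estimated correlation), with 0 adjusted over the list alone; the call ended without control day 21 replicate 1 (0.395) or IFN day 21 replicate 1 (0.0527). The cholesterol synthesis genes had a median of -0.47 (adjusted p = 0.0179, and adjusted p = 0.642 with an estimated correlation), with 0 adjusted over the list alone; the call ended without control day 21 replicate 1 (0.509) or IFN day 21 replicate 1 (0.0538).

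Over all genes at day 21, edgeR called 172, 145 higher and 27 lower with IFN, and DESeq2 called 635, 351 higher and 284 lower. No filter gave 443 higher and 596 lower, so the excess of higher calls was not kept. The groups did not overlap for 39.5% of genes, where chance gives 33.3%. All 172 called genes were among these, so leaving out 1 library could hardly turn their direction. Without control day 21 replicate 1, the control at day 21 was replicate 2 alone, the library set apart by stress genes. The count was 3865 without control day 21 replicate 1 (2144 higher and 1721 lower), 113 without IFN day 0 replicate 1, 107 without either IFN day 14 library, and 63 and 60 without IFN day 21 replicate 1 or 2. Of the 21 named genes called at day 21, between 10 and 21 kept the call when 1 library was left out, the fewest without IFN day 21 replicate 1 (10) or replicate 2 (11), and 17 without control day 21 replicate 2 or IFN day 14 replicate 1; 0 changed direction.

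At day 0 the arms were close. The only called gene was Bpifc, a lipid-binding family member (chromosome 10, 85959340 to 86011895), with 65 counts in the control libraries and 0 in the IFN libraries, at least 20.78-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.0223). Its call held without control day 0 replicate 2, control day 21 replicate 1 or control day 21 replicate 2 and was lost in the other 9 fits that leave out a library, with adjusted p up to 0.35. Irf7 was at 4.30 ± 1.70 CPM in the IFN arm and 2.76 ± 0.0966 CPM in control, and these genes did not pass: Col1a1 (0.52 ± 0.41), Alpl (0.69 ± 0.69), Bglap (0.84 ± 1.01), Sp7 (0.17 ± 0.36), Runx2 (0.03 ± 0.21), Ifnar1 (-0.02 ± 0.23) and Ifnar2 (0.08 ± 0.19). Over all genes 1 was called, 381 had an unadjusted p below 0.05, and 36.2% did not overlap, where chance gives 33.3%. The count was 50 without control day 0 replicate 2, 1 without either control day 21 library and 0 without any other single library.

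The interferon-stimulated list was positive in 49 of 53 members at day 0, with 0 called either over all genes or adjusted over the list alone. Its median was 0.46 (camera adjusted p = 8.16e-08, and adjusted p = 0.784 with an estimated correlation). Without control day 0 replicate 1 the median was 0.10 and the adjusted p = 0.164. The MHC class I (median 0.23), fibroblast (0.34), adipocyte (-0.45), cell cycle (-0.59), cholesterol synthesis (-0.86) and immediate early (0.56) lists also passed camera at day 0. Each of these 6 calls ended without control day 0 replicate 1 (adjusted p = 0.948 for each), and none held with an estimated correlation (lowest adjusted p = 0.784). The adipocyte call also ended without control day 21 replicate 1 (0.0808), control day 21 replicate 2 (0.13) or IFN day 0 replicate 2 (0.0548). Control day 0 replicate 1 had a median log2 CPM of 6.32 over the cell cycle genes and 5.83 over the cholesterol genes, against 5.35 and 4.05 in replicate 2. The spread between control day 0 replicate 2 and the IFN day 0 libraries (chi-square per degree of freedom 8.936 and 6.077) was near that between the 2 IFN day 0 libraries (5.824), and that between the 2 control libraries was 228.5.

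Averaged over the 3 days, IFN against control gave 331 calls, 231 higher and 100 lower. The highest were Slfn4 (log2 4.90 ± 0.71), Irf7 (4.42 ± 0.21), Rsad2 (4.41 ± 0.34), Tgtp1 (4.34 ± 0.42) and Ifi213 (4.31 ± 0.73), and the lowest Fmod (-2.99 ± 0.52), Tnn (-2.44 ± 0.19), the dipeptidase Dpep1 (-2.28 ± 0.40) and Mrgprf (-1.87 ± 0.28), leaving out Bpifc, whose fitted value rests on 0 counts in IFN day 0. Ifi213 (adjusted p up to 0.713) and Fmod kept the call in 7 of the 12 fits that leave out a library. Dpep1 kept it in 9. Slfn4 kept it in 11 and had an adjusted p = 1 without IFN day 0 replicate 1. In these fits log2 ranged from 3.36 to 6.22 for Slfn4 and from 3.22 to 5.44 for Ifi213. DESeq2 called 828, 391 higher and 437 lower. More were lower as well with no filter (445 higher and 716 lower), without control day 21 replicate 1 (922 and 945) and without both outlying control libraries (874 and 892). The count was 1867 and 781 without control day 21 replicate 1 or 2, 187 and 189 without IFN day 0 replicate 1 or 2, 186 and 189 without IFN day 14 replicate 1 or 2, and 196 and 197 without IFN day 21 replicate 1 or 2.

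Differentiation itself was read in the control arm, day 14 against day 0. Ibsp rose from 0 counts to 1135, at least 414-fold higher against a floor of 3 counts over the group (adjusted p = 0.00172). The collagenase gene Mmp13 (chromosome 9, 7272514 to 7283331) rose from 8.11 ± 2.64 to 117.4 ± 36.1 CPM (log2 3.85 ± 0.34, adjusted p = 0.000365), and Sp7, the osteoblast transcription factor osterix (chromosome 15, 102356606 to 102367182), from 5.29 ± 1.96 to 22.3 ± 8.58 CPM (log2 2.07 ± 0.37, adjusted p = 0.0185). These were the 3 of 25 osteoblast genes that rose, with 0 lower and 5 higher adjusted over the list alone. Alpl, alkaline phosphatase, was at 15.4 ± 6.72 against 1.75 ± 1.69 CPM and did not pass (log2 3.12 ± 0.72, adjusted p = 0.053). Alpl did pass with DESeq2 (adjusted p = 8.04e-05), no filter (7.25e-14), a replicate block (0.0405) or library size alone (0.0493). It also passed without control day 0 replicate 2 (0.0271), without control day 21 replicate 1 (0.0163) or 2 (0.0155) and without both outlying control libraries (0.00493). Values for Runx2 (-0.02 ± 0.21), Col1a1 (0.30 ± 0.41), Bglap (0.08 ± 1.03), Sox9 (0.18 ± 0.22), Ifnar1 (-0.31 ± 0.23) and Ifnar2 (-0.06 ± 0.19) did not pass either. Sox9 passed without both outlying control libraries (adjusted p = 0.0294). The osteoblast list had a median of 0.30 (camera adjusted p = 0.0293, and adjusted p = 0.73 with an estimated correlation); its call ended without control day 0 replicate 1 (0.264), control day 14 replicate 2 (0.0555), control day 21 replicate 1 (0.0996) or control day 21 replicate 2 (0.102). The Sp7 call ended without control day 0 replicate 1 or control day 14 replicate 2 (adjusted p up to 0.127).

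After Ibsp, and among genes with more than 3 counts in each group, the highest named folds at control day 14 were those of the transcription factor Zbtb16 (log2 9.40 ± 0.70), Dpep1 (7.85 ± 0.55) and the secreted Wnt inhibitor Wif1 (7.52 ± 0.70). Their order rests on single libraries. With 1 library left out, Zbtb16 ranged from 8.58 to 13.37, Dpep1 from 7.48 to 8.15 and Wif1 from 6.69 to 11.48, the highest without control day 0 replicate 2 for Zbtb16 and Wif1. Sash3 had 449 counts at day 14 and 2 at day 0, a ratio of 245.7 (95% interval 67.61 to 2035), and Orm1, an acute-phase protein gene, had 363 and 2, a ratio of 198.6 (54.59 to 1646). Among the lowest was the proteoglycan gene Lum, with 352 counts at day 0 and 0 at day 14, at least 107.2-fold lower over pooled counts (counting error only). The 2 day 0 libraries disagreed (4.47 ± 5.72 CPM), so the size of the Lum fold rests mostly on 1 of them. Ptprz1 (-4.85 ± 1.04), the anion transporter Slc26a7 (-4.63 ± 0.72), Atp1b1 (-4.50 ± 0.53), the Wnt antagonist Sfrp2 (-4.44 ± 0.89) and Pdzd2 (-3.54 ± 0.40) followed. With 1 library left out, Ptprz1 ranged from -10.5 (without control day 14 replicate 2) to -3.70, Slc26a7 from -5.40 to -3.85, Atp1b1 from -5.39 to -3.96 and Sfrp2 from -5.66 to -2.44. Matrix processing genes were among those higher, with Mmp11 (1.99 ± 0.25), the collagen cross-linking enzyme Lox (2.25 ± 0.32) and Plod2 (2.13 ± 0.42) among 4 higher and 1 lower of 25, and 7 higher and 4 lower adjusted over the list alone. Of 22 Wnt genes 4 rose, among them Lrp5 (1.64 ± 0.20) and Ccn5 (1.10 ± 0.19), and 1 fell, with 8 higher and 3 lower adjusted over the list alone. Sfrp2 and Plod2 kept the call in 3 of the 12 fits that leave out a library. Lum and Ptprz1 kept it in 4, Sash3 and Ccn5 in 9 and Slc26a7 in 11.

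Other control day 14 calls lay in several lists. Fabp4 (log2 3.66 ± 0.35) rose among 10 adipocyte markers, 2 adjusted over the list alone. Comp (2.48 ± 0.53) rose among 17 chondrocyte genes, 1 adjusted over the list alone. Postn (1.72 ± 0.37) and Pdgfra (0.94 ± 0.21) rose and Lum fell among 15 fibroblast markers, with 4 higher and 4 lower adjusted over the list alone; the median was 0.23 and the mean -0.40. Ccn2 (1.94 ± 0.36) rose among 24 BMP and TGF-beta genes, 6 adjusted over the list alone. The anti-apoptotic gene Bcl2l1 (0.99 ± 0.18) rose among 22 p53 and apoptosis genes, with 5 higher and 2 lower adjusted over the list alone; the median was -0.02 and the mean 0.17. Of 24 inflammatory genes, Lcn2 (4.40 ± 0.57) rose and Ccl7 (-2.03 ± 0.40) fell, with 2 higher and 3 lower adjusted over the list alone. The smooth muscle actin gene Acta2 (-2.33 ± 0.52) fell among 9 muscle markers, with 1 higher and 3 lower adjusted over the list alone, and the Notch ligand Dll1 (-2.40 ± 0.42) fell among 10 Notch genes, with 1 higher and 2 lower adjusted over the list alone. Oas3 (4.83 ± 0.70) rose and Ifitm3 (-1.09 ± 0.25) fell among 53 interferon-stimulated genes, with 9 higher and 1 lower adjusted over the list alone. Comp kept the call in 2 of the 12 fits that leave out a library. Acta2, Pdgfra and Ifitm3 kept it in 3, and Postn, Bcl2l1 and Ccl7 in 4. Ccn2 and Dll1 kept it in 9, and Oas3 and Lcn2 in 11.

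No cell cycle gene was called in the control arm at day 14 against day 0. All 30 had a negative fold change from day 0 to day 14, with a median of -1.04, although edgeR called 0 of them over all genes and 0 adjusted over the list alone (camera adjusted p = 5.16e-10, and adjusted p = 0.73 with an estimated correlation). Without control day 0 replicate 1 the median was -0.43 and the adjusted p = 0.00375. All 24 glycolysis and hypoxia genes were positive, with a median of 1.21; Bnip3 was the 1 call (log2 3.18 ± 0.65), and 20 were higher adjusted over the list alone (camera adjusted p = 5.32e-10, and adjusted p = 0.73 with an estimated correlation). Without control day 14 replicate 1, the library with 626.4 CPM of Bnip3, the list median was 0.30 with an adjusted p = 0.000478, and the Bnip3 call was lost (log2 1.20). The Bnip3 call held in 1 of the 12 fits that leave out a library, with adjusted p up to 0.223.

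Several further lists passed camera at control day 14, none of them with an estimated correlation. The interferon-stimulated list had a median of 0.46 (camera adjusted p = 0.0235, and adjusted p = 0.73 with an estimated correlation), and its call ended without control day 0 replicate 1 (0.777) or control day 14 replicate 2 (0.525, direction down). MHC class I genes had a median of 0.37 with 0 called (0.0499, and adjusted p = 0.73 with an estimated correlation), lost without the same 2 libraries (0.999 and 0.661). The chondrocyte list had a median of 0.50 (0.0293, and adjusted p = 0.497 with an estimated correlation), lost without control day 0 replicate 1 (0.243) or control day 14 replicate 2 (0.0588). The BMP and TGF-beta list had a median of 0.25 (0.0293, and adjusted p = 0.497 with an estimated correlation), lost without control day 0 replicate 1 (0.0505) or 2 (0.0925) or control day 14 replicate 1 (0.0764) or 2 (0.0555). Ribosomal protein genes (median 0.31, 0.00133), cholesterol synthesis genes (median -0.58, 0.0364) and immediate early and heat shock genes (median -1.38, 0.0235) had 0 called over all genes and 0 adjusted over the list alone, each with adjusted p = 0.73 with an estimated correlation. The ribosomal call ended without control day 0 replicate 1 (0.147), the cholesterol call without control day 0 replicate 1 (0.285) or control day 14 replicate 2 (0.698), and the immediate early call without control day 0 replicate 2 (0.577) or control day 14 replicate 2 (0.122).

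Over all genes, edgeR called 411 between control day 14 and day 0, 268 higher and 143 lower, and DESeq2 called 1243. The spread used was pooled with the tighter IFN libraries (biological coefficient of variation 0.28 over both arms, 0.392 in control), which favours calls here. Fewer genes were called with only the groups compared, as given under the dependence on processing. The control day 14 libraries also entered the IFN effect at day 14. Opposite calls in both, as for Ibsp, Lrp5, Fabp4 and Ccl7, are therefore not independent. More were lower than higher without control day 21 replicate 1 (767 higher and 777 lower) and without both outlying control libraries (909 and 957). The groups did not overlap for 42.5% of genes, where chance gives 33.3%. All 411 called genes were among these, so leaving out 1 library could hardly turn their direction. The count was 199 without control day 0 replicate 1, 159 without control day 14 replicate 1, 1544 and 1548 without control day 21 replicate 1 or 2, 194 and 196 without IFN day 0 replicate 1 or 2, 194 without either IFN day 14 library, and 213 without either IFN day 21 library. Of the 32 named genes called here, 17 kept the call without control day 0 replicate 1 or control day 14 replicate 1, 21 without control day 0 replicate 2, 24 without control day 14 replicate 2, 31 without either control day 21 library and 20 without any 1 of the 6 IFN libraries; 0 changed direction.

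Between day 14 and day 21 the control arm gave 5 calls, 3 higher and 2 lower, as many as the 5 called in simulated data with nothing changed and the unequal spread of the arms. The epidermal growth factor family ligand Ereg (log2 4.10 ± 0.47) and the protease inhibitor Serpinb2 (4.09 ± 0.49) rose, and the transcription factor Maf (-1.60 ± 0.16) and the calcium channel subunit Cacna1a (-1.51 ± 0.17) fell. Serpinb2 kept its call in 5 of the 12 fits that leave out a library. Ereg kept it in 8, and Maf and Cacna1a in 9. With only the groups compared 0 genes were called, and adjusted p was 0.812 for each of these 4. Values for Sox9 (0.03 ± 0.22), Col1a1 (0.50 ± 0.41), Sp7 (-0.86 ± 0.36), Alpl (0.34 ± 0.65), Bglap (2.63 ± 1.02), Runx2 (-0.31 ± 0.22), Ifnar1 (-0.12 ± 0.23) and Ifnar2 (-0.24 ± 0.19) did not pass. Bglap, Ifnar1, Sp7 and Ifnar2 passed without control day 21 replicate 1. The day 21 group was then replicate 2 alone, the library with 25680 CPM of Hspa5, so those passes rest on that library. Bglap also passed with no filter (0.0025) and turned sign without control day 21 replicate 2 (log2 -0.98). The share of higher calls moved with library size as the only scaling, from 3 of 5 to 5 higher and 2 lower of 7. The groups did not overlap for 37.5% of genes, where chance gives 33.3%; 3074 genes had an unadjusted p below 0.05 and DESeq2 called 844. The edgeR count was 13 and 14 without control day 0 replicate 1 or 2, 18 and 14 without control day 14 replicate 1 or 2, 4779 (2162 higher and 2617 lower) and 36 without control day 21 replicate 1 or 2, and 0 without IFN day 0 replicate 2 or either IFN day 14 library.

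In this step, 2 lists of stress genes had positive values in all members. All 20 endoplasmic reticulum stress genes were positive at control day 21 against day 14 (median 2.45, camera adjusted p = 7.32e-07, and adjusted p = 0.71 with an estimated correlation), as were all 20 immediate early and heat shock genes (median 2.74, camera adjusted p = 5.88e-08, and adjusted p = 0.71 with an estimated correlation); edgeR called 0 of either list, and 16 and 14 were higher adjusted over the list alone. Without control day 21 replicate 2 the endoplasmic reticulum stress list had a median of -0.10 and an adjusted p = 0.176, and the immediate early and heat shock list a median of 0.35 and an adjusted p = 0.000142. The mineralization list (median 0.40, camera adjusted p = 0.0199, and adjusted p = 0.71 with an estimated correlation) had 0 calls and 2 higher adjusted over the list alone; its call ended without control day 0 replicate 1 (0.0528), control day 0 replicate 2 (0.0532), control day 14 replicate 2 (0.452) or control day 21 replicate 1 (0.112). Ribosomal protein genes had a median of 0.24 (camera adjusted p = 0.00995, and adjusted p = 0.776 with an estimated correlation) with 0 called either way; the call ended without control day 14 replicate 2 (0.0514) or control day 21 replicate 2 (0.176, direction down).

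In the IFN arm, day 14 against day 0 gave 1857 calls, 895 higher and 962 lower. More were higher with only the groups compared (4712 higher and 4449 lower), library weights (4449 and 4282) and without both outlying control libraries (2961 and 2785). The same held without control day 0 replicate 2 (1080 and 1065), control day 21 replicate 2 (1968 and 1906) or IFN day 14 replicate 1 (300 and 165) or 2 (314 and 165). Oasl1 rose from 0 to 2679 counts, at least 915.6-fold higher against 3 counts over the group, the keratin gene Krt23 from 0 to 558 (at least 190.7-fold) and H2-M9 from 0 to 306 (at least 104.6-fold). Ifi209 rose by log2 11.05 ± 1.115, and Ifi214 had 3211 counts against 2, a ratio of 1646 (95% interval 455.3 to 13600); both belong to a family of close copies whose reads counting could split. Sfrp2 (-6.78 ± 1.02), Slc26a7 (-6.64 ± 0.81), Lum (-6.53 ± 1.34), the immediate early gene Fosb (-5.83 ± 1.60) and the chemokine Ppbp (-5.56 ± 1.08) were lowest. Of 53 interferon-stimulated genes, 50 rose and 1 fell (51 and 1 adjusted over the list alone). Of 25 osteoblast genes 3 rose and 6 fell (4 and 9 adjusted over the list alone), and of 25 collagen processing genes 4 rose and 8 fell (5 and 10 adjusted over the list alone). The groups did not overlap for 74.4% of genes, where chance gives 33.3%; the spread used for this test was pooled with the wider control libraries. The count was 3820 and 3874 without control day 21 replicate 1 or 2, 470 and 478 without IFN day 0 replicate 1 or 2, 465 and 479 without IFN day 14 replicate 1 or 2, and 1235 and 1228 without IFN day 21 replicate 1 or 2. Fosb lost its call in 10 of the 12 fits that leave out a library, Lum without any IFN library of day 0 or day 14, Ifi214 without either IFN day 0 library, Ppbp without IFN day 0 replicate 1 or either IFN day 14 library (adjusted p up to 0.125) and Sfrp2 without IFN day 14 replicate 1 (0.0575).

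Between day 14 and day 21 in the IFN arm no gene passed edgeR in the main fit, whose spread is pooled with that of the control libraries. All 15 measured mineralization genes were positive, with a median of 1.35 (camera adjusted p = 3.76e-12, and adjusted p = 0.0752 with an estimated correlation; fry adjusted p = 0.0342) and 5 higher adjusted over the list alone. Ibsp was at 7.87 ± 2.16 CPM at day 21 and 1.44 ± 1.16 CPM at day 14 (log2 2.43 ± 0.61, adjusted p = 0.488), and Sox9 had a log2 fold change of 0.70 ± 0.22 (adjusted p = 0.636). Of 53 interferon-stimulated genes 4 were positive, with a median of -0.55 (camera adjusted p = 9.38e-19, and adjusted p = 0.27 with an estimated correlation) and 0 called either way. Over all genes edgeR called 0 (lowest adjusted p = 0.154), 1131 had an unadjusted p below 0.05, and DESeq2 called 114. The groups did not overlap for 60.1% of genes, where chance gives 33.3%. The count was 3 without either control day 14 library, 104 and 100 without control day 21 replicate 1 or 2, 4502 with only the groups compared and 2748 in limma voom with library quality weights.

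The IFN effects at day 14 and day 21 were compared across genes, using separate libraries for the group means. The spread of each gene came from all libraries for both effects. Genes of low spread are called more readily in both, so shared calls can exceed the numbers for independent lists without shared effects. Their log2 fold changes correlated with Pearson r = 0.354 and Spearman rho = 0.232 (covariance 0.359) across 17289 genes, which are not independent replicates. Without any single library r lay between 0.15 and 0.289, in fits that also keep more genes of low count. Of the 396 genes called at day 14, 376 (94.9%) had the same sign at day 21; 123 were called higher at both days against 1.88 for independent lists, and 15 lower at both against 0.269. The day 0 effect had r = 0.00443 with day 14 and 0.0534 with day 21.

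The IFN effect was also set against control differentiation, again with separate libraries for the group means and a spread per gene from all libraries. An excess of shared calls over the numbers for independent lists can therefore arise without shared effects. The day 14 IFN effect and the control change from day 0 to day 21 had r = 0.0801 and rho = 0.135 (covariance 0.108). Of their calls, 45 genes were higher in both against 8.55 for independent lists, 24 lower in both against 4.52, 26 lower with IFN and higher with differentiation against 6.57, and 5 the other way round against 5.88. For the day 21 IFN effect and the control change from day 0 to day 14, r was -0.0317 and rho 0.00223 (covariance -0.0354). Of their calls, 4 genes were higher in both against 2.25 for independent lists, 2 lower in both against 0.223, 6 lower with IFN and higher with differentiation against 0.419, and 3 the other way round against 1.2. Without any single library the first r lay between 0.029 and 0.147, lowest without control day 21 replicate 2, and the second between -0.0546 and 0.0257, with its sign turned without control day 0 replicate 2, control day 14 replicate 1 or control day 21 replicate 2.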

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

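The tests of technical explanations in this part were chosen after the results were seen, except those on chance splits, whose predictions were written before their values. The IFN effect differed between day 14 and day 0, by a test of the difference itself, for 103 genes, 75 higher and 28 lower (edgeR adjusted p below 0.05). Bpifc was fitted at log2 8.92 (adjusted p = 0.00309), but IFN day 0 had 0 counts of it, so the size is not known and it is not ranked. The highest other differences were those of Pax5 (log2 6.66, adjusted p = 0.00371), Irf7 (6.57, adjusted p = 0.000969), Ifit3 (6.37, adjusted p = 0.0125) and Ifit3b (6.23, adjusted p = 0.0248). The lowest were those of Megf6 (-4.79, adjusted p = 0.0257), Draxin (-4.62, adjusted p = 0.0451), Tnn (-4.05, adjusted p = 0.00377), Mrgprf (-3.79, adjusted p = 0.0418) and Tnc (-3.54, adjusted p = 0.0198). Mrgprf kept its call in 3 of the 12 fits that leave out a library. Draxin and Ifit3b kept it in 4, Megf6 in 6, Tnc in 7 and Ifit3 in 8. In these fits log2 ranged from 5.65 to 7.86 for Ifit3 and from 5.38 to 8.58 for Ifit3b. Of 53 interferon-stimulated genes, 32 had a higher effect at day 14 (50 higher and 1 lower adjusted over the list alone; median 3.42, camera adjusted p = 6.44e-67, and adjusted p = 0.126 with an estimated correlation). More differences were lower than higher with no filter (360 higher and 469 lower), library weights (257 and 334), without control day 0 replicate 2 (226 and 266) and without control day 21 replicate 1 (171 and 183) or 2 (170 and 174). The count of 103 was 492 without control day 0 replicate 2, 40 and 204 without control day 14 replicate 1 or 2, 354 and 344 without control day 21 replicate 1 or 2, 18 and 16 without IFN day 0 replicate 1 or 2, 20 and 19 without IFN day 14 replicate 1 or 2, and 36 without either IFN day 21 library. Between day 21 and day 14 edgeR called 0 differences, with 1315 genes at an unadjusted p below 0.05; the count was 2584 without control day 21 replicate 1, and DESeq2 called 31.

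Splits of the libraries within days were drawn to ask how many calls arise for the average IFN effect when arms are mixed. Of 100 splits with the real one, 4 called at least as many genes as the real 331, with a highest other count of 389. The other splits that called 299 or more kept the day 14 and day 21 arms together and mixed or swapped the day 0 arms alone. The next highest count was 1. The split that swapped the day 0 arms called 386, so the count did not rest on the day 0 labels.

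Control day 21 replicate 2 differed from replicate 1 by a median log2 of 3.71 over 20 endoplasmic reticulum stress genes and 3.19 over 20 immediate early and heat shock genes. Carry-over of ribosomal RNA does not account for it, since the log2 ratio of CT010467.1 was -5.32. A mislabelled IFN library does not either, since the interferon-stimulated list differed by a median of -0.353 where IFN libraries differ by 3. RNA of another cell type could not be told apart, with a highest median of 1.11 among the lists of other cell types, for muscle, and a half-range of 0.912. The muscle list was near the floor, with a median log2 CPM of 0.81 in replicate 1 and 0.79 in replicate 2, so it cannot decide. No biological explanation was tested.

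Col1a1 was lower with IFN at day 14 and day 21; this pattern was narrowed from bone matrix genes to Col1a1 after its test value was seen. A single outlying control library does not account for it, since the log2 fold change lay between -3.06 and -1.84 in every fit that leaves out a library. More RNA of other cell types in the IFN libraries cannot be told apart. It would lower the other osteoblast genes about as much as Col1a1, and the median log2 fold change of 24 of them at day 14 was -0.69, with an interquartile half-range of 0.783 that reaches the upper 95% bound of -1.33 for Col1a1. At day 21 the median was -0.28, with a half-range of 0.768 that stays above the bound of -1.70, but several members are near the floor of counts, so that day is left open too. This test replaced one on 36 markers of other cell types at day 14 (median -0.43), most of them near the floor. No biological explanation was tested.

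The day 0 libraries of the IFN arm showed almost no interferon response. The median log2 difference of the interferon-stimulated list was 0.0947 from control day 0 replicate 2 and 0.764 from replicate 1. A bootstrap over list genes gave an SE of 0.0411 for the first, which does not measure spread between cultures. Neither difference neared the day 14 median of 3.71. Whether spread between the control day 0 libraries hides a smaller response cannot be told, since the 2 controls disagree. The limit for this test was set after the results were seen, and with a list median of 0.46 its outcome was nearly fixed. The low values may mean that the IFN day 0 libraries were taken before IFN was added, which the labels do not say.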

How the results depend on the processing

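The fit without the 2 outlying control libraries and the fit with library weights were tests chosen after the results were seen. Every one of the 124 called named results kept its direction under every setting run on named genes, which leaves out the stricter filter and the library weights; the call was kept by 124 with DESeq2, RLE scaling or no filter, 111 with library size alone, 109 without both outlying control libraries and 65 of 114 with only the groups compared. The kept direction is weak evidence, since every called gene in a comparison of 2 groups had no overlap between them. Leaving out a library could hardly turn such a gene, and the other settings refit the same counts. In a replicate block fit, 108 kept the call and the counts of calls were 0, 331 and 147 for IFN at days 0, 14 and 21, 288 on average, 310 and 5 for the control steps, 1641 and 0 for the IFN steps, and 72 and 0 for the changes of the IFN effect. The cause of each difference below was not tested, except that no filter tests more genes and leaving libraries out both removes data and keeps more genes of low count. With library size alone, the median of all genes moved to 0.129 from -0.011 for IFN at day 21, to -0.137 from 0.00135 for control day 21 against 14, and to 0.123 from 0.0237 for the later change of the IFN effect. Genes of low count are limited by depth.

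Counts of calls moved as follows. With DESeq2: 998 and 635 for IFN at days 14 and 21, 828 on average, 1243 and 844 for the control steps, 2913 and 114 for the IFN steps, 476 and 31 for the changes of the IFN effect. With no filter on low counts: 88, 1175 and 1039 for IFN at days 0, 14 and 21, 1161 on average, 1503 and 1426 for the control steps, 274 for the later IFN step, 829 and 386 for the changes. With only the groups compared: 0, 657 and 25 for IFN by day, 105 and 0 for the control steps, 9161 and 4502 for the IFN steps; the change from day 0 to day 14 gave 137. Without both outlying control libraries: 0, 2751 and 868 for IFN by day, 1766 on average, 1866 and 716 for the control steps, 5746 and 741 for the IFN steps, 601 and 96 for the changes. With library weights: 0 and 1667 for IFN at days 0 and 14, 8731 and 2748 for the IFN steps, 591 for the earlier change. With library size alone the earlier change gave 62, and with an absolute log2 fold change of at least 1 the average gave 197. The correlation of the IFN effects at day 14 and day 21 was 0.534 with the stricter filter and 0.293 without both outlying libraries, and that of the day 14 effect with control differentiation 0.037.

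Without both outlying control libraries these uncalled genes changed sign: at day 0 Alpl -0.0437, Runx2 -0.0232, Sox9 0.051 and Sp7 -0.16; at day 21 Alpl 0.23, Bglap 2.21 and Ifnar2 -0.0265; for control day 14 against day 0 Bglap -0.17 and Col1a1 -0.17; for control day 21 against day 14 Alpl -0.78, Bglap -0.98 and Ifnar1 0.22. With library size alone Ifnar1 at day 0 was 0.00472 and Sox9 in control day 21 against day 14 was -0.10. Lists that turned direction without both libraries had adjusted p of 0.617 (MHC class I, day 0), 0.838 (fibroblast, day 0), 0.00174 (endoplasmic reticulum stress, day 21), 0.0178 (ribosomal, day 21), 0.264 (cholesterol, control day 14), 0.0967 (endoplasmic reticulum stress, control day 21) and 0.135 (ribosomal, control day 21).

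With 1 library left out, counts lay in these ranges: IFN at day 0 0 to 50, day 14 114 to 1197, day 21 60 to 3865, average 186 to 1867; control steps 159 to 1548 and 0 to 4779; IFN steps 465 to 3874 and 0 to 104; changes of the IFN effect 16 to 492 and 0 to 2584. The correlations lay between 0.15 and 0.289 for the 2 IFN effects, 0.029 and 0.147 for day 14 against differentiation, and -0.0546 and 0.0257 for day 21 against differentiation. Genes that changed sign ranged at day 0 over -0.0354 to 2.36 (Alpl), -0.0423 to 0.0154 (Ifnar1), -0.0169 to 0.0879 (Runx2), -0.66 to 0.0571 (Sox9) and -0.16 to 0.61 (Sp7); at day 14 over -0.0377 to 0.0882 (Ifnar2) and -0.41 to 0.27 (Runx2); at day 21 over -1.48 to 0.23 (Alpl), -2.31 to 2.21 (Bglap), -0.61 to 0.23 (Ifnar1) and -0.0268 to 0.49 (Ifnar2). For control day 14 against day 0 they ranged over -0.46 to 0.46 (Bglap), -0.17 to 1.03 (Col1a1), -0.11 to 0.00455 (Ifnar2), -0.40 to 0.29 (Runx2) and -0.13 to 0.59 (Sox9), and for control day 21 against day 14 over -0.78 to 0.93 (Alpl), -0.98 to 3.54 (Bglap), -0.0705 to 0.92 (Col1a1), -0.61 to 0.22 (Ifnar1), -0.63 to 0.0567 (Runx2) and -0.12 to 0.17 (Sox9). List adjusted p ranged over 2.34e-05 to 0.948 (MHC class I, day 0), 1.54e-05 to 0.211 (ribosomal, day 21), 6.52e-26 to 0.00846 (endoplasmic reticulum stress, day 21), 0.000135 to 0.999 (MHC class I, control day 14), 8.01e-09 to 0.698 (cholesterol, control day 14), 4.43e-13 to 0.777 (interferon-stimulated, control day 14), 1.52e-05 to 0.176 (ribosomal, control day 21) and 2.88e-25 to 0.176 (endoplasmic reticulum stress, control day 21).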

Other observations

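The test in this part was chosen after the first results were seen, and its gene list was set before the values of its members were looked at. In the IFN arm, 2 genes chosen after their values were seen had higher values at day 21 than at day 14. Dmp1, an osteocyte matrix protein, was at 457.7 ± 9.63 CPM at day 21 and 17.98 ± 3.50 CPM at day 14 (log2 4.67 ± 1.17, adjusted p = 0.442). Spp1, osteopontin, was at 13640 ± 593 against 4959 ± 16 CPM (log2 1.46 ± 0.29, adjusted p = 0.246). In the control libraries Dmp1 ranged from 4.338 to 86.5 CPM with no order by day. Neither gene passed edgeR.

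Zbtb16 and Fkbp5, known glucocorticoid targets, were chosen after their values were seen. At day 14 Zbtb16 was at 39.7 ± 24.6 CPM in control and 20.6 CPM with IFN, and Fkbp5 at 859.9 ± 237 and 562.6 ± 26.5 CPM. The hypothesis was a glucocorticoid in the differentiation medium, which the labels do not describe. A second list of 16 targets, 14 measured, had a median of 1.57 in control, with 11 positive and 6 higher (camera p = 0.0151 with an estimated correlation), and 1.31 in the IFN arm, with 12 positive and 7 higher (p = 0.079 with an estimated correlation). The larger p, 0.079, misses the limit set in advance, so the test could not tell.

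The ribosomal RNA gene CT010467.1 ranged from 99.28 to 21080 CPM over the libraries, with 8633 and 99.28 CPM in the control day 14 pair and 5917 and 147.6 CPM in the control day 21 pair. Fos was at 2.216 CPM in control day 0 replicate 1 and 407.5 CPM in replicate 2. Hmox1 was at 8577 CPM in control day 21 replicate 2 and 277.4 CPM in replicate 1, and Atf3 at 847.2 and 22.08 CPM.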
